A study of Drosophila melanogaster with 8 samples.

How the data were processed

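Libraries of polyadenylated RNA from 4 separate culture flasks each of ML-DmD17-c3 and S2-DRSC cells were made with a stranded mRNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The 8 libraries were grouped by the cell line named in their labels, and replicate numbers were taken from the same labels.

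The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.3a, featureCounts, Subread 2.0.0, DESeq2 1.30.1 and RSEM and the builds BDGP6 and dm6, without saying which step each performed; per the file headers, the tables have the layout of RSEM gene results. The authors deposited, per the file headers, 1 table per library with expected counts, TPM, FPKM, length and effective length for 17730 genes. Whether counting used strand is not given in the sources used here, so genes with a partner on the opposite strand may hold its reads. The deposited expected counts are estimated counts that RSEM assigns in part across genes, and 16.8% to 18.2% of them were not whole. The deposited TPM values sum to about 1000000 per library and keep no depth. The deposited FPKM values were checked against expected count over effective length and total, equalled it at 99.44% or more of the nonzero genes in each library within rounding, and entered no test. No row lacked a gene name. Positions were taken from an Ensembl annotation of BDGP6 that held 17633 of the 17730 gene identifiers, and the 97 others, among them Nplp2, have no position here.

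Total expected counts ran from 76822525 to 110163700. A floor of 3 counts equalled 0.0272 to 0.0391 CPM of a library's total, and 0.0328 CPM in S2-DRSC and 0.0333 CPM in D17-c3 on the scale used for folds. Libraries hold reads without molecular identifiers, so floors cover counting error only. The chi-square of counts over genes between replicates was at least 8.26 per degree of freedom, so no replicates agreed within sampling noise.

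Expected counts were rounded and tested with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filterByExpr, design by line, all 8 libraries, prior degrees of freedom 3.23, common biological coefficient of variation 0.187), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values were counts over TMM-scaled library sizes. SEs were computed as the absolute log2 fold change over the square root of the F statistic. Of the tested genes, 181 had counts identical to those of another tested gene. Where a line had 0 counts, the fold was computed against the floor. Data were simulated from the S2-DRSC means and the library sizes over 11606 genes, of which 11406 were left unchanged. The test recovered 28.4% of genes changed 1.41-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold. It called 0.0614% of unchanged genes. In the real comparison 75.2% of tested genes were called, so these shares need not hold there.

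A set of 32 gene lists (Polycomb and Trithorax groups, Hox genes, developmental regulators, cell types and pathways) was fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. That rule names all measured Hox, PRC1 and PRC2 genes, the 10 genes per direction with the largest fitted fold change among called genes with at least 20 CPM in the higher line and no overlap of the lines, and the 2 called members per direction with the largest fold change of each other list. Other members named beside them, the heat shock values per library, the stretches of neighbouring genes and the genes around p24-2 and CG18853 were chosen after their values were seen. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and with fry as an alternative, adjusted over the lists. None of the 9 lists that passed with the preset correlation passed with the estimated one. In simulation with genes drawn independently, a planted list passed all 3 and 0 of 30 unchanged lists did. Such data hold no correlation between genes, so they cannot decide between the preset and the estimated correlation. In the real data, the estimated correlations of the 9 lists ran from 0.0173 (developmental regulators) to 0.825 (ribosomal proteins), all above the preset 0.01. Genes on in 1 line only had at least 1 CPM in its 4 libraries and under 0.1 CPM in the other's, and lists with 5 or more members in the background were tested for enrichment. X-linked and autosomal genes were compared by 1 value per library with a two-sided exact permutation test. Windows held 50 genes of at least 0 mean log2 CPM, in steps of 10. In 5 simulated gene orders a planted stretch of 100 genes raised by 1 log2 unit was found each time. That rise lies well above the window limit of 0.5, so smaller or shorter shifts were not covered. Without planting, at most 3 of 813 windows were shifted in a run, and with planting 6 shifted windows lay outside the planted stretch over the 5 runs.

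Alternatives were median-of-ratios size factors, library totals only, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a fit with the replicate number as a block, each library left out, an adjusted p of 0.01, a test against a 2-fold change and other limits for genes on or off. A test on TPM after TMM scaling was added after seeing the data. Scripts ran under R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.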

Results

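Polyadenylated RNA was sequenced from a pair of Drosophila melanogaster cell lines, with 4 libraries per line made from separate culture flasks. ML-DmD17-c3 (D17-c3) is a line derived from imaginal discs, and S2-DRSC is a stock of S2, an embryonic line with features of hemocytes, the fly's blood cells. The series is about Polycomb group proteins and related factors, so the comparison asks how the transcriptomes of the lines differ and which of these regulators and of the developmental genes they act on each line expressed. Total expected counts were 91074700, 86658763, 76822525 and 85428208 in D17-c3 replicates 1 to 4, and 95239626, 110163700, 98664867 and 83612326 in S2-DRSC replicates 1 to 4. Between 13667 and 14503 of the 17730 genes had counts above 0 in a library, and eEF1alpha1, a translation elongation factor gene, took the largest share in each (1.33% to 1.69%). Levels are given as mean counts per 1000000 (CPM) ± SD over 4 libraries per line, and fold changes as log2 of D17-c3 over S2-DRSC ± SE.

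The transcriptomes differed in most genes. D17-c3 expressed the single genes en, hh, ci and Egfr and the genes of the E(spl) complex at levels far above S2-DRSC. S2-DRSC expressed the collagen IV genes vkg and Col4a1, the hemocyte gene Hml and 12 of 14 antimicrobial peptide genes at higher levels than D17-c3. Of 11606 genes tested, 4533 were higher in D17-c3 and 4192 were higher in S2-DRSC at an adjusted p under 0.05, and 2968 and 2020 of them differed at least 2-fold by fitted fold change. In a test against a 2-fold change, 2499 and 1619 genes passed. The 2968 fell to 1921 with a filter of 1 CPM in 4 libraries and to 1625 on TPM after TMM scaling, and the 2020 to 1113 on log2(TPM + 1). The libraries of the lines did not overlap at 71.6% of the tested genes, where chance would separate 2.86%. The first principal component of log2 CPM held 92.3% of the variance and separated the lines. Correlations of log2 CPM were 0.9943 to 0.9967 within S2-DRSC, 0.9764 to 0.9953 within D17-c3 and 0.843 to 0.8526 between the lines. D17-c3 replicate 2 was the least similar to its group, with a mean correlation of 0.9801 with the others. The split of the calls depended on the scaling: 52% of them were higher in D17-c3 here, against 60% with library totals only, 62.9% in both tests on unscaled TPM and 50.6% on TPM after TMM scaling, a test added after seeing the data. The median log2 fold change of all genes was 0.04 here and 0.21, 0.18, 0.25 and 0.01 in these alternatives.

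The genes with the largest differences toward D17-c3 among those with at least 20 CPM included several developmental transcription factor genes. Their log2 fold changes ran from 9.04 to 9.33. They were sNPF, a neuropeptide gene at 120 ± 25.3 CPM against 0.187 ± 0.0642, CG4766, mab-21, the forkhead gene croc at 486 ± 67 CPM, the noncoding RNA lncRNA:yar, E(spl)m6-BFM, the T-box gene bi at 67.1 ± 4.01 CPM, the LIM homeobox gene Awh, the lipid droplet gene Lsd-2, and en at 46.4 ± 11.4 CPM against 0.0852 ± 0.0319. CG4766 (X, 5997508 to 6000797) and mab-21 (X, 6008183 to 6013181) are neighbours, at 204 ± 39.3 and 223 ± 37.5 CPM in D17-c3. Awh was unevenly expressed there, with 5.46 CPM in replicate 2 and a mean of 40.5 CPM in the other libraries.

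Toward S2-DRSC, the largest difference was that of CG18853 (2R, 7829062 to 7830429), which had 70.4 ± 2.97 CPM there and 0 counts in each D17-c3 library, at least 2112-fold higher against a floor of 3 counts per library. The others were p24-2, CG7408, Nplp2, Unc-115b, the myofilin gene Mf, the transporter gene Oatp58Dc, CG15478, CecA1 and the cytochrome P450 gene Cyp12c1, with log2 fold changes from -10.06 to -8.33. Nplp2 reached 1916 ± 286 CPM in S2-DRSC against 3.53 ± 0.38, and Oatp58Dc 592 ± 12.2 against 1.39 ± 0.126. The genes p24-2 (3R, 9687402 to 9692794) and Unc-115b (3R, 9687060 to 9692775) overlap on the same strand and have the paralogs eca and Unc-115a close by, so their counts are uncertain. CG18853 overlaps CG30382 on the opposite strand, and whether it has a close copy elsewhere was not checked, so its 0 counts are uncertain too. Its neighbours phr (49.1 ± 11.2 against 86.2 ± 3.93 CPM), Prosalpha1 (9.72 ± 4.69 against 40.7 ± 6.59 CPM) and CG30382 (174 ± 23.7 against 374 ± 32.7 CPM) were also lower in D17-c3.

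Polycomb repressive complex genes were expressed in both lines and differed modestly. Of the 7 PRC1 genes tested, 5 were higher in D17-c3 and 1 in S2-DRSC, or 2 in S2-DRSC without S2-DRSC replicate 4. The largest differences were those of Psc (log2 1.53 ± 0.09, 228 ± 26 against 79 ± 5.11 CPM, adjusted p = 4.07e-07) and ph-p (log2 1.48 ± 0.10, 216 ± 31.6 against 77.4 ± 1.97 CPM). The tandem copy ph-d (log2 0.69 ± 0.08), Sce (0.51 ± 0.08), the histone H2A ubiquitin ligase gene of the complex, and Su(z)2 (0.22 ± 0.07) were also higher in D17-c3. Pc, which encodes the chromodomain subunit, was higher in S2-DRSC (log2 -0.72 ± 0.07, 22.5 ± 1.27 against 37 ± 1.32 CPM), and Scm was at 75.6 ± 3.51 and 83.7 ± 7.34 CPM with no call (adjusted p = 0.107). Reads of ph-p and ph-d could be split between the copies, so each value is uncertain. As a set, the PRC1 genes did not pass the camera test against other genes (adjusted p = 0.331). Of all tested genes 75.2% had a call, so calls for most members of this or a later list are not particular to it.

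Among 8 PRC2 genes, 3 were higher in D17-c3 and 4 in S2-DRSC. The methyltransferase gene E(z) was higher in D17-c3 (log2 0.47 ± 0.06, 78.3 ± 4.22 against 56.5 ± 0.92 CPM), as were Su(z)12 (0.34 ± 0.08) and jing (0.53 ± 0.09). Caf1-55 (log2 -1.02 ± 0.17, 132 ± 32.8 against 268 ± 15.1 CPM), esc (-0.57 ± 0.10), Jarid2 (-0.32 ± 0.11) and Pcl (-0.28 ± 0.08) were higher in S2-DRSC, and escl had no call (20.1 ± 2.72 and 22.4 ± 0.512 CPM). The set test gave an adjusted p of 0.787. The number of PRC2 genes higher in S2-DRSC fell from 4 to 2, with Jarid2 and Pcl losing their calls, with library totals only, with a filter of 1 CPM in 4 libraries and in both tests on unscaled TPM.

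**Figure D1:**
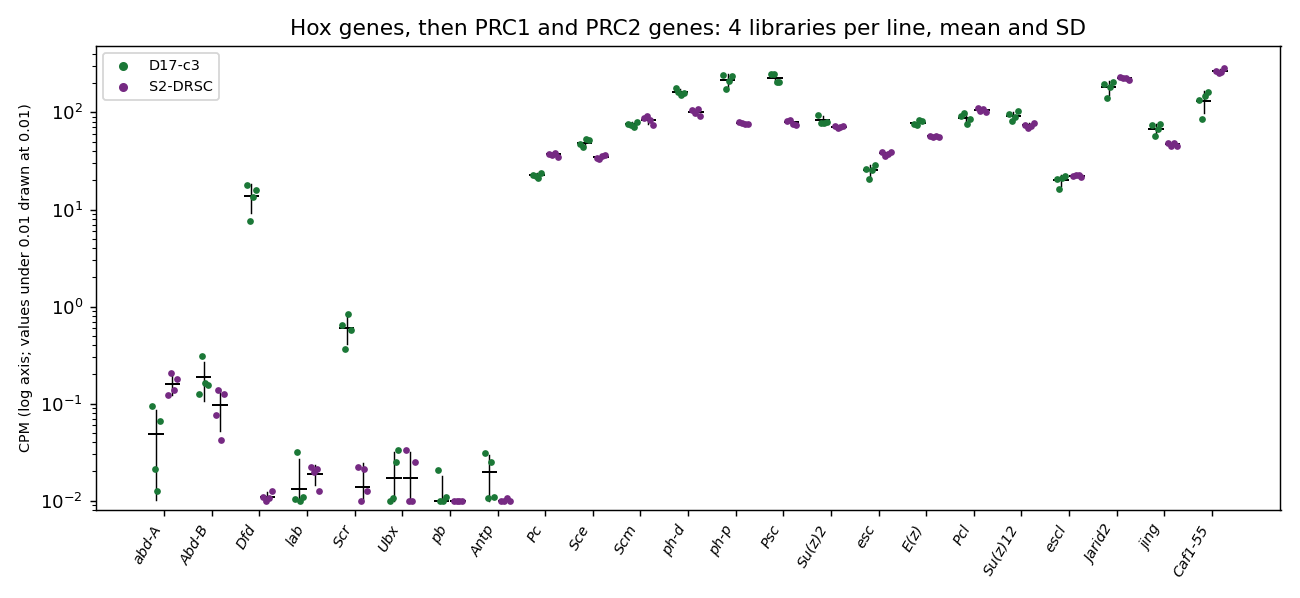
CPM of the Hox, PRC1 and PRC2 genes in the 4 D17-c3 (green) and 4 S2-DRSC (purple) libraries, on a log axis with values under 0.01 drawn at 0.01; points are libraries, and black lines are the mean and SD. Dfd lies at 13.7 CPM in D17-c3 and Scr at 0.606 CPM, the other Hox genes stay under 1 CPM in both lines, and all PRC1 and PRC2 genes lie above 10 CPM.

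Of 11 genes for proteins that bind Polycomb response elements, 4 were higher in each line, but those in S2-DRSC fell to 2 with library totals only and to 0 in both tests on unscaled TPM. The largest differences toward D17-c3 were those of grh (log2 3.88 ± 0.18, 22.2 ± 4.43 against 1.51 ± 0.197 CPM) and psq (1.99 ± 0.13), and toward S2-DRSC those of phol (-0.46 ± 0.08) and Adf1 (-0.34 ± 0.07). Of 9 other Polycomb-associated genes, 5 were higher in D17-c3, led by corto (log2 5.08 ± 0.14, 161 ± 24.1 against 4.78 ± 0.499 CPM) and calypso (0.28 ± 0.08), and 1, lolal (-0.84 ± 0.06), in S2-DRSC. The count of 5 fell to 3 with median-of-ratios size factors, with no filter, with the replicate number as a block and on TPM after TMM scaling. It also fell to 3 without D17-c3 replicate 1 or 4 or any 1 S2-DRSC library. Of 14 Trithorax group genes, 2 were higher in D17-c3, trx (0.52 ± 0.08) and skd (0.19 ± 0.07), and 6 in S2-DRSC, with mor (-0.91 ± 0.09) and trr (-0.87 ± 0.07) leading. In the tests on unscaled TPM, 5 (pseudocount 1) or 6 (pseudocount 0.1) Trithorax group genes were higher in D17-c3 and 3 in S2-DRSC. The 2 genes higher in D17-c3 became 5 with library totals only, and fell to 1 with no filter, with the replicate number as a block, and without D17-c3 replicate 1 or 4 or any 1 S2-DRSC library. None of these sets passed the camera test (adjusted p = 0.75, 0.608 and 0.331).

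Hox genes, classical Polycomb targets that specify segment identity, were low or at the detection floor in both lines except for Dfd and, at a low level, Scr in D17-c3. Dfd (3R, 6791836 to 6802428) had 13.7 ± 4.45 CPM in D17-c3 and 4 counts in all S2-DRSC libraries together (log2 10.12 ± 0.42, adjusted p = 3.59e-08). Scr was at 0.606 ± 0.198 CPM in D17-c3, with 34 to 67 counts per library, against 0 to 2 counts per S2-DRSC library (log2 5.33 ± 0.51), and it overlaps noncoding RNA genes on both strands. Dfd and Scr were under the floor of 3 counts in every S2-DRSC library, so the sizes of their fold changes and the SEs are uncertain. abd-A was slightly higher in S2-DRSC (0.0484 ± 0.0383 against 0.161 ± 0.0383 CPM), a call that ended in each of the tests on TPM. Abd-B (0.188 ± 0.0824 and 0.0959 ± 0.0443 CPM) had no call (adjusted p = 0.062). Ubx, Antp, lab and pb had at most 3 counts in any library and were not tested, so a difference in them was not detectable at this depth. The Hox set, with 4 of 8 members tested, gave an adjusted p of 0.331, and with a filter of 1 CPM in 4 libraries only Dfd was called.

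Developmental regulators were mostly higher in D17-c3. Of 75 genes on this list 42 were tested, 31 were higher in D17-c3 and 9 in S2-DRSC, all at least 2-fold, with a median log2 fold change of 2.85. The leading genes toward D17-c3 were bi and Awh, and those toward S2-DRSC were ap (0.191 ± 0.0986 against 4.99 ± 0.0755 CPM) and sna (0.0297 ± 0.0246 against 0.473 ± 0.136 CPM). Of 36 wing and haltere disc genes tested, which share 23 list members with the regulators, 26 were higher in D17-c3, led by bi and en, and 7 in S2-DRSC, again led by ap and sna. Some of the 26 were low in D17-c3, such as vg (1.41 ± 0.778 CPM), nub (0.274 ± 0.0557) and rn (0.154 ± 0.0459). Others, such as sd (396 ± 20.2 CPM) and salr (30.9 ± 11.2), were not. Both lists passed the camera test (adjusted p = 0.00111 each), and neither did with an estimated correlation (adjusted p = 0.231 and 0.53). In D17-c3 replicate 2, Awh, en and croc were lower than in the other D17-c3 libraries (en 29.5 CPM against a mean of 52.1). With a filter of 1 CPM in 4 libraries, 17 regulators were called higher in D17-c3 and 4 in S2-DRSC, and 4 disc genes were higher in S2-DRSC.

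Notch pathway genes were mostly higher in D17-c3. Of 18 Notch pathway genes, 13 were higher in D17-c3, each at least 2-fold, and 1 was higher in S2-DRSC, the coactivator gene mam (log2 -0.23 ± 0.07). That call ended with library totals only, with a filter of 1 CPM in 4 libraries and in both tests on unscaled TPM. With DESeq2 and without D17-c3 replicate 1 or 4, 2 were higher in S2-DRSC. All genes of the E(spl) complex on the list, direct targets of Notch signalling, were higher in D17-c3. E(spl)m3-HLH reached 776 ± 232 CPM against 4.96 ± 1.11, E(spl)mbeta-HLH 717 ± 195 against 10.6 ± 1.07, and E(spl)m6-BFM 77.6 ± 15.7 against 0.135 ± 0.028. E(spl)m4-BFM had 0 counts in S2-DRSC and was at least 37.9-fold higher in D17-c3. The ligand gene Dl (log2 4.01 ± 0.17) and fng (2.87 ± 0.20), which encodes a glycosyltransferase that modifies Notch, were higher too, while N itself was at 268 ± 57.4 and 328 ± 13.4 CPM with no call (adjusted p = 0.0879). The median log2 fold change was 7.01, or 6.45 with E(spl)m4-BFM at its bound. The list passed the camera test (adjusted p = 0.000648), and with an estimated correlation its adjusted p was 0.619.

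Other signalling pathways differed in both directions. Of 11 Hedgehog pathway genes, 7 were higher in D17-c3, led by the ligand gene hh (114 ± 39.2 against 0.569 ± 0.055 CPM) and the transcription factor gene ci (369 ± 37.9 against 2.22 ± 0.306 CPM), and 2 in S2-DRSC, boi (log2 -2.79 ± 0.19) and cos (-0.67 ± 0.09). Of 19 Wnt pathway genes, 9 were higher in D17-c3, led by wg (4.28 ± 2.24 against 0.108 ± 0.0352 CPM) and Wnt6 (log2 4.39 ± 0.63), and 5 in S2-DRSC, led by fz3 (-3.38 ± 0.29) and Wnt2 (-1.65 ± 0.32), or 3 with a filter of 1 CPM in 4 libraries. Of 14 BMP pathway genes, 8 were higher in D17-c3, led by dlp (136 ± 27.1 against 21 ± 0.996 CPM) and cv-2 (1.58 ± 0.20), and 6 in S2-DRSC, led by sog (-4.74 ± 0.19) and dpp (-1.43 ± 0.20). Of 13 EGFR pathway genes, 3 were higher in D17-c3 and 7 in S2-DRSC. The receptor gene Egfr itself (2R, 21522420 to 21559977) stood at 354 ± 137 CPM in D17-c3, 151 CPM in replicate 2 and a mean of 421 CPM in the others, against 0.965 ± 0.14 in S2-DRSC. vn (1.84 ± 0.12) followed it, and grk (-2.35 ± 0.10) and aos (-1.86 ± 0.14) led toward S2-DRSC. Of 8 JAK/STAT pathway genes, 4 were higher in D17-c3, led by et (2.27 ± 0.31) and upd3 (1.23 ± 0.23), and 2 in S2-DRSC, Stat92E (-0.26 ± 0.08) and dome (-0.22 ± 0.08). Both calls ended with library totals only, with a filter of 1 CPM in 4 libraries and in both tests on unscaled TPM. Only 1 was left with the replicate block and without D17-c3 replicate 3 or S2-DRSC replicate 1, 2 or 3. None of these sets passed the camera test (adjusted p = 0.121, 0.331, 0.794, 0.331 and 0.715 in this order), and the EGFR list had a median log2 of -0.31 and a mean of 0.10, with the test downward.

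Genes of the ecdysone response, the steroid hormone pathway that drives moulting, numbered 11 higher in D17-c3 and 4 in S2-DRSC of 20 tested (camera adjusted p = 0.165). br, a zinc finger transcription factor gene, reached 1152 ± 155 CPM in D17-c3 against 19.9 ± 3.19, and ImpL1 3.32 ± 0.741 against 0.0262 ± 0.0158. Eip78C (log2 -1.31 ± 0.43) and usp (-0.75 ± 0.06) led toward S2-DRSC.

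Hemocyte genes differed in both directions. Of 19 tested, 6 were higher in D17-c3 and 9 in S2-DRSC (camera adjusted p = 0.117), or 6 and 13 without D17-c3 replicate 2. That library had a list median of 0.05, against -0.62, -0.58 and -1.02 in D17-c3 replicates 1, 3 and 4 (log2 relative to all libraries). Hml, Pxn and Tig were higher in S2-DRSC with Nplp2 and the collagen IV gene vkg (log2 -7.55 ± 0.17), and Hml stood at 2995 ± 210 against 253 ± 89.5 CPM. The blood cell transcription factor gene srp was expressed in both lines (401 ± 36.3 and 321 ± 11.4 CPM, log2 0.32 ± 0.08). gcm, near the floor (log2 3.26 ± 0.54), and the scavenger receptor gene Sr-CI (3.08 ± 0.51) led toward D17-c3. Sr-CI was at 45.2 CPM in D17-c3 replicate 2 and a mean of 11.9 CPM in the other D17-c3 libraries. Of 6 crystal cell and lamellocyte genes, 3 were higher in D17-c3, led by peb (5.24 ± 0.14) and PPO1 (1.57 ± 0.48), and 1 in S2-DRSC, PPO2 (-4.40 ± 0.36), or 3 without D17-c3 replicate 2 and 2 with DESeq2, limma-voom or the replicate block (adjusted p = 0.784).

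Most antimicrobial peptide genes and most Toll and Imd pathway genes were higher in S2-DRSC. Of 14 antimicrobial peptide genes, 12 were higher in S2-DRSC and 0 in D17-c3, with a median log2 fold change of -6.78. The cecropin genes CecA1 (72.6 ± 13.4 against 0.218 ± 0.041 CPM) and CecA2 (33.1 ± 6.83 against 0.107 ± 0.0351 CPM) led, and AttC and CecC had no call. DptB was at 65.5 ± 26.3 CPM in S2-DRSC and Dro at 36.1 ± 6.95. In S2-DRSC replicate 4 the median of the list was 3.72, against a mean of 3.02 in the other S2-DRSC libraries (log2 relative to all libraries). Cecropin and attacin genes have close copies, so counts of single members are uncertain. Of 24 Toll and Imd pathway genes, 17 were higher in S2-DRSC, led by the peptidoglycan receptor genes PGRP-LA (log2 -6.12 ± 0.18) and PGRP-LC (-5.56 ± 0.25), and 2 in D17-c3, PGRP-SC2 (7.06 ± 0.17) and PGRP-LE (4.63 ± 0.13). Both lists passed the camera test (adjusted p = 5.04e-05 and 0.00111), and with an estimated correlation the adjusted p-values were 0.53 and 0.231.

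Epithelial junction genes were mostly higher in D17-c3, with 13 of 20 higher there and 2 in S2-DRSC (camera adjusted p = 0.0139, or 0.706 with an estimated correlation). The septate junction genes vari (log2 3.31 ± 0.13) and bou (7.47 ± 1.61 against 1.07 ± 0.146 CPM) led, and the E-cadherin gene shg was at 125 ± 14.9 against 22.6 ± 1.07 CPM. The apical polarity gene crb (log2 -1.84 ± 0.12) and Fas3 (-1.07 ± 0.24) were higher in S2-DRSC. Extracellular matrix and integrin genes split 8 to 8 among 18 (adjusted p = 0.645), and 5 of the list's members also stand on the hemocyte list. The perlecan gene trol (1153 ± 409 against 113 ± 5.06 CPM) and Timp (log2 3.12 ± 0.26) led toward D17-c3, vkg and Col4a1 (2850 ± 27.1 against 15.6 ± 3.83 CPM) toward S2-DRSC. The median of this list was above 0 (0.17) while its mean (-0.89) and its test pointed downward.

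Genes of other tissues were mixed. Of 18 myoblast and muscle genes, 12 were higher in D17-c3 and 1 in S2-DRSC, bt (log2 -0.56 ± 0.18). That call ended with library totals only, in both tests on unscaled TPM and without S2-DRSC replicate 3. With no filter and without D17-c3 replicate 2, the genes higher in S2-DRSC numbered 2. With a filter of 1 CPM in 4 libraries the 12 fell to 6. The list passed the camera test (adjusted p = 0.023, or 0.53 with an estimated correlation). The members that led were stumps (375 ± 44.2 against 1.18 ± 0.179 CPM) and htl (log2 4.04 ± 0.14), which encode an adaptor and a receptor of FGF signalling. Of 5 tracheal genes, 4 were higher in D17-c3, led by the FGF receptor gene btl (307 ± 83.2 against 2.57 ± 0.353 CPM) and verm (19.6 ± 14.4 against 0.646 ± 0.0598 CPM), and 0 in S2-DRSC (adjusted p = 0.0742). Of 11 neuronal genes, 3 were higher in D17-c3, led by fne (4.91 ± 0.19) and cac (2.85 ± 0.17), and 4 in S2-DRSC, led by the active zone gene brp (-5.40 ± 0.14) and para (-1.76 ± 0.24), with a median of -0.36, a mean of 0.18 and a test downward (adjusted p = 0.811). Of 6 glial genes, 3 were higher in D17-c3 (1 with a filter of 1 CPM in 4 libraries), led by wrapper (6.22 ± 0.19) and repo (1.49 ± 0.38), and 2 in S2-DRSC, Gs2 (-3.01 ± 0.18) and moody (-2.49 ± 0.21), with an adjusted p of 0.811. The gene repo was low in both lines (0.208 ± 0.0729 against 0.0741 ± 0.0298 CPM). Of 16 germline and piRNA genes, 5 were higher in D17-c3, led by qin (4.21 ± 0.19) and vas (2.37 ± 0.26), and 6 in S2-DRSC, led by the innexin gene zpg (-7.08 ± 0.26) and AGO3 (-2.80 ± 0.12), with an adjusted p of 0.684. Levels of vas were low (0.43 ± 0.045 against 0.0819 ± 0.0242 CPM), and it overlaps solo on the same strand and vig on the opposite strand. Of 5 fat body genes tested, 4 were higher in D17-c3, led by Yp1 (2.63 ± 0.47) and apolpp (2.46 ± 0.17), and 1 in S2-DRSC, Lsp1gamma (-5.76 ± 0.20), or 2 with no filter and without D17-c3 replicate 1 or S2-DRSC replicate 4, with an adjusted p of 0.331. Yp1 was low too (0.908 ± 0.209 against 0.143 ± 0.101 CPM).

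Dosage compensation genes, which act on the X chromosome of male cells, were mostly higher in S2-DRSC. Of 8 tested, 6 were higher there and 1, mle (log2 0.23 ± 0.07), in D17-c3, a call that ended with no filter and without D17-c3 replicate 1 or 4 or S2-DRSC replicate 1, 2 or 4, while 2 were higher in D17-c3 on log2(TPM + 1). The noncoding RNAs lncRNA:roX2 (35 ± 1.90 against 0.493 ± 0.0917 CPM) and lncRNA:roX1 (11.5 ± 1.38 against 0.721 ± 0.0415 CPM) led, and msl-2 (86.3 ± 3.79 against 26.4 ± 1.79 CPM) and mof (85.6 ± 3.32 against 31.3 ± 3.64 CPM) followed. The list passed the camera test (adjusted p = 0.0215), and with an estimated correlation its adjusted p was 0.619. Of 6 sex determination genes, 3 were higher in D17-c3, led by fru (log2 1.34 ± 0.16) and Sxl (446 ± 116 against 220 ± 29.6 CPM), and 1 in S2-DRSC, tra (-0.28 ± 0.11), which lost its call under several alternatives and changed sign in both tests on unscaled TPM (adjusted p of the set 0.715).

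Relative to autosomal genes, X-linked genes were slightly lower in D17-c3. The median deviation of 1929 X-linked genes minus that of 9521 autosomal genes was -0.0207 ± 0.0134 on the log2 scale in D17-c3 and 0.0189 ± 0.0136 in S2-DRSC (SD, n = 4), a difference of -0.0397 or 0.973-fold (two-sided exact permutation test, p = 0.0286, the smallest the 70 assignments can give). Without D17-c3 replicate 1, 2 or 4 or S2-DRSC replicate 3 the exact p was 0.0571. By arm, the median log2 difference relative to all genes was 0.06 on 2L, -0.09 on 2R, 0.10 on 3L, -0.03 on 3R, 0.11 on 4 and -0.03 on X. These medians used genes of at least 0 mean log2 CPM, 1468 of them on X. The autosomal arms 2R and 3R thus lay at or below X, so the small difference was not particular to the X. The exact test asked only whether the libraries separated by line.

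Along the arms, differences clustered. In a description chosen after seeing the data, 97 of 813 windows of 50 neighbouring genes had a median shifted by at least 0.5 on the log2 scale, 65 toward D17-c3 and 32 toward S2-DRSC. They merged into 24 stretches. The longest spanned 300 genes on 3L (11061571 to 15954797, from Blos2 to Pka-C3, median log2 0.77, 79.3% of genes higher in D17-c3), and 170 genes on 2R (22329195 to 23975408, from CG34207 to mr) had a median of 0.79. On X, 160 genes (11430523 to 13744683, from Evi5 to CG11134) were lower in D17-c3, with a median of -0.52.

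**Figure D2:**
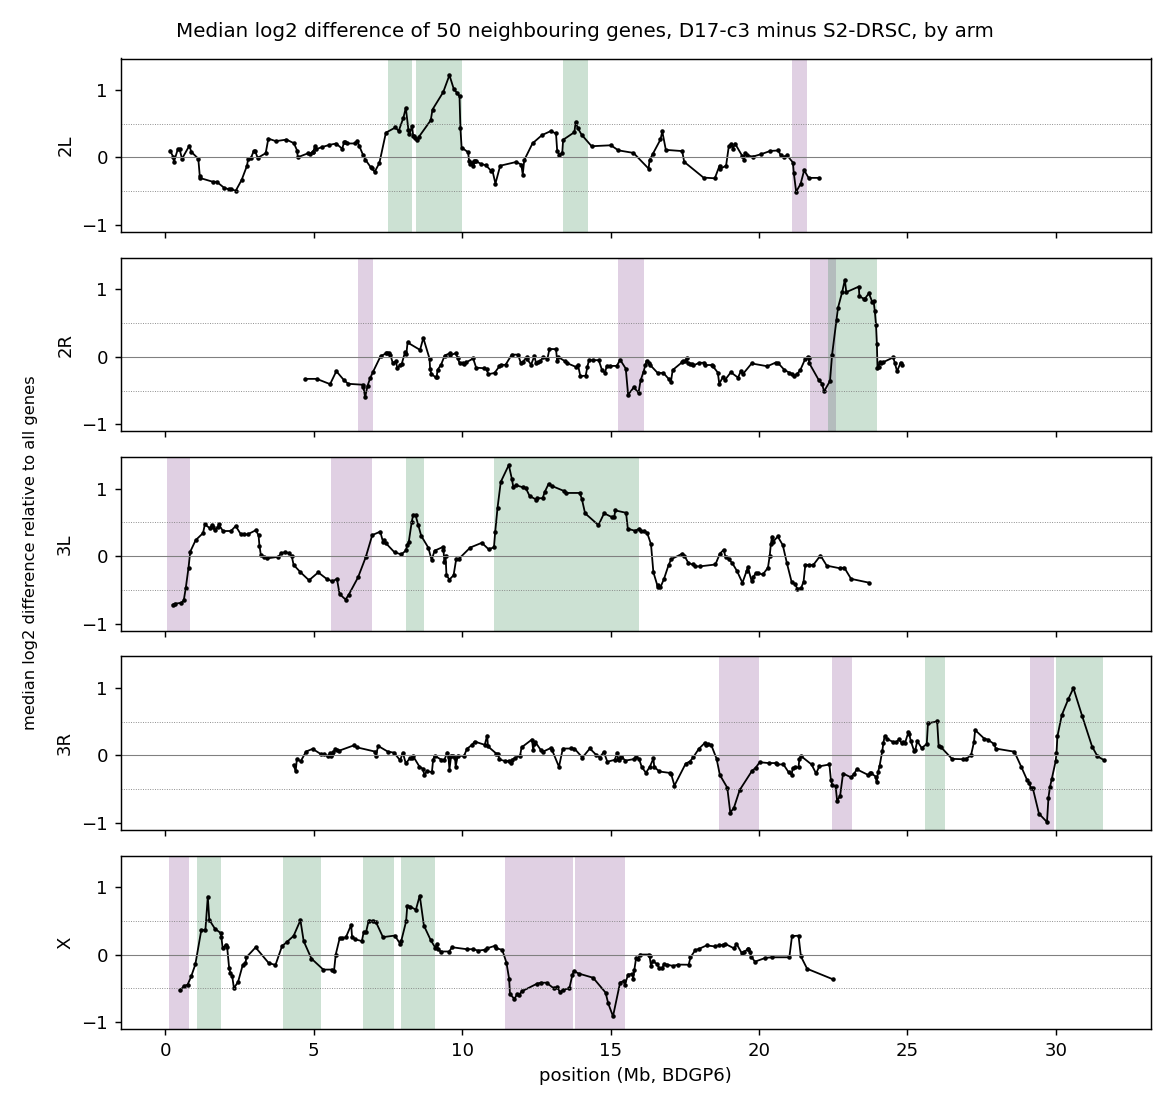
Median log2 difference (D17-c3 minus S2-DRSC, relative to all genes) of 50 neighbouring genes against their position in Mb (BDGP6), 1 panel per chromosome arm; dotted lines mark 0.5 and -0.5, and shading marks merged stretches higher in D17-c3 (green) or in S2-DRSC (purple). The longest shaded stretch lies on 3L from 11.06 to 15.95 Mb.

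Most heat shock genes were higher in D17-c3, and most had their highest D17-c3 level in replicate 2. Of 12 tested, 11 were higher in D17-c3 and 1 in S2-DRSC (camera adjusted p = 0.0742, or 0.791 with an estimated correlation), and 9 and 1 without D17-c3 replicate 2. Hsp23 was at 8564 CPM in replicate 2 and 3176 ± 406 (SD, n = 3) in the other D17-c3 libraries, against 111 ± 41.5 in S2-DRSC. Hsp26 was at 2384 and 509 ± 28 CPM in the same libraries, and Hsp83 at 9740 and 3782 ± 228. In all, 11 of the 12 genes were higher in replicate 2 than in every other D17-c3 library. In S2-DRSC, replicate 2 was also the highest library and replicate 4 the lowest for all 12 genes, as with Hsp26 (96.2, 139, 73.3 and 50.2 CPM in replicates 1 to 4). The set passed without D17-c3 replicate 1 or 3 or S2-DRSC replicate 2 (adjusted p = 0.0481, 0.033 and 0.041 with the preset correlation, against an adjusted p = 0.791 with an estimated correlation on all libraries). It also passed with the replicate number as a block (camera adjusted p = 0.0246 with the preset correlation). Hsp70Bc (log2 3.91 ± 0.63) followed Hsp23 in size, and Hsp70Ba, 1 of several near-identical copies that share reads, was higher in S2-DRSC (-6.11 ± 0.66).

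**Figure D3:**
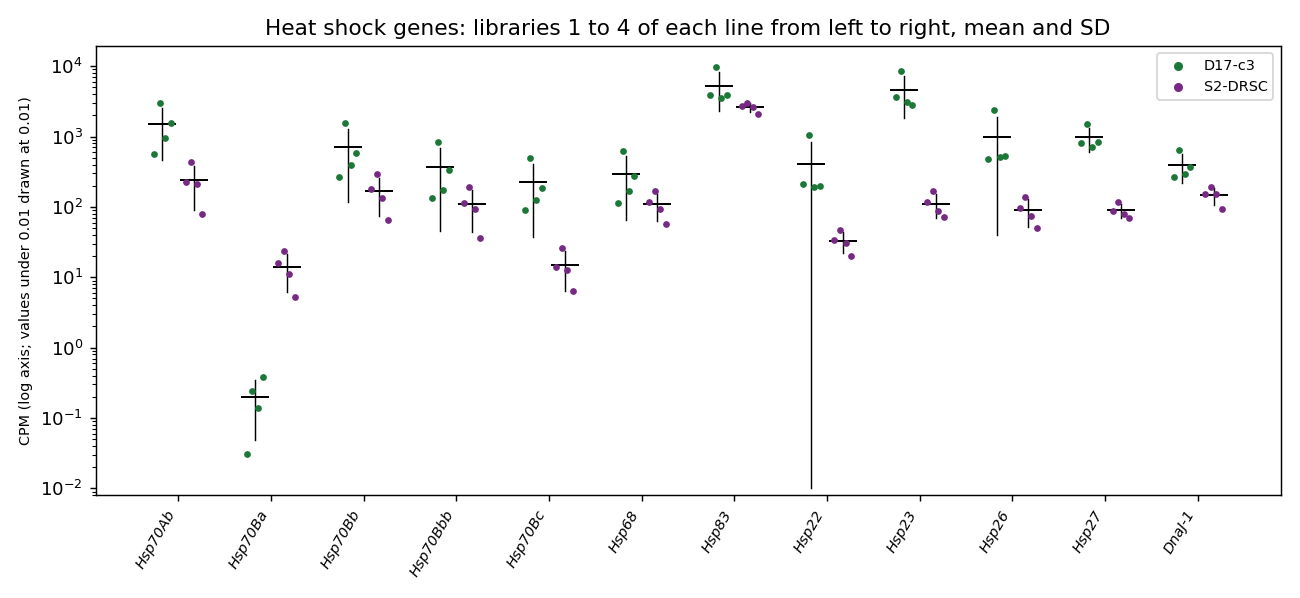
CPM of the heat shock genes in the 4 D17-c3 (green) and 4 S2-DRSC (purple) libraries, replicates 1 to 4 from left to right, on a log axis; black lines are the mean and SD, and an SD that reaches below 0.01 ends there. Hsp23 reaches 8564 CPM in D17-c3 replicate 2 and 111 CPM on average in S2-DRSC.

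Cell cycle and ribosomal protein genes with a call were mostly higher in S2-DRSC. Of 21 cell cycle genes, 14 were higher in S2-DRSC, led by the replication licensing genes Mcm5 (log2 -1.45 ± 0.24) and Mcm3 (-1.21 ± 0.23), and 3 in D17-c3, led by polo (0.59 ± 0.11) and CycB3 (0.37 ± 0.14), whose call ended under several alternatives (camera adjusted p = 0.0742). The 3 fell to 1 when any single library other than D17-c3 replicate 2 was left out, and the set passed without D17-c3 replicate 4 (adjusted p = 0.0448 with the preset correlation, against an adjusted p = 0.791 with an estimated correlation on all libraries). The set also passed with the replicate number as a block (camera adjusted p = 0.0314 with the preset correlation). D17-c3 replicate 2 stood apart, with a cell cycle list median of -0.89 against -0.29, -0.10 and -0.05 in D17-c3 replicates 1, 3 and 4 (log2 relative to all libraries), and without it 16 cell cycle genes were higher in S2-DRSC and 3 in D17-c3. Its ribosomal list median was -0.68, against -0.15, 0.13 and -0.22 in D17-c3 replicates 1, 3 and 4 and 0.15 to 0.32 in S2-DRSC. Of 89 cytosolic ribosomal protein genes, 46 were higher in S2-DRSC, 4 were higher in D17-c3 and 39 had no call, or 47 higher in S2-DRSC and 9 in D17-c3 without D17-c3 replicate 2, and 2 in D17-c3 with a filter of 1 CPM in 4 libraries, with a median log2 of -0.43 (camera adjusted p = 0.00111, or 0.791 with an estimated correlation). RpL37a (732 ± 58 against 3229 ± 83 CPM) and RpS19b (-1.82 ± 0.23) led toward S2-DRSC, and the minor paralogs RpL22-like (3.59 ± 0.67) and RpS5b (3.10 ± 0.28) toward D17-c3.

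Adjusted over the list alone, the counts of higher genes in D17-c3 and S2-DRSC were 3 and 1 for Hox, 6 and 10 for hemocyte, 3 and 17 for Toll and Imd, 11 and 5 for ecdysone and 3 and 0 for sex determination genes, and those of the other 27 of the 32 lists equalled the counts given above.

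**Figure D4:**
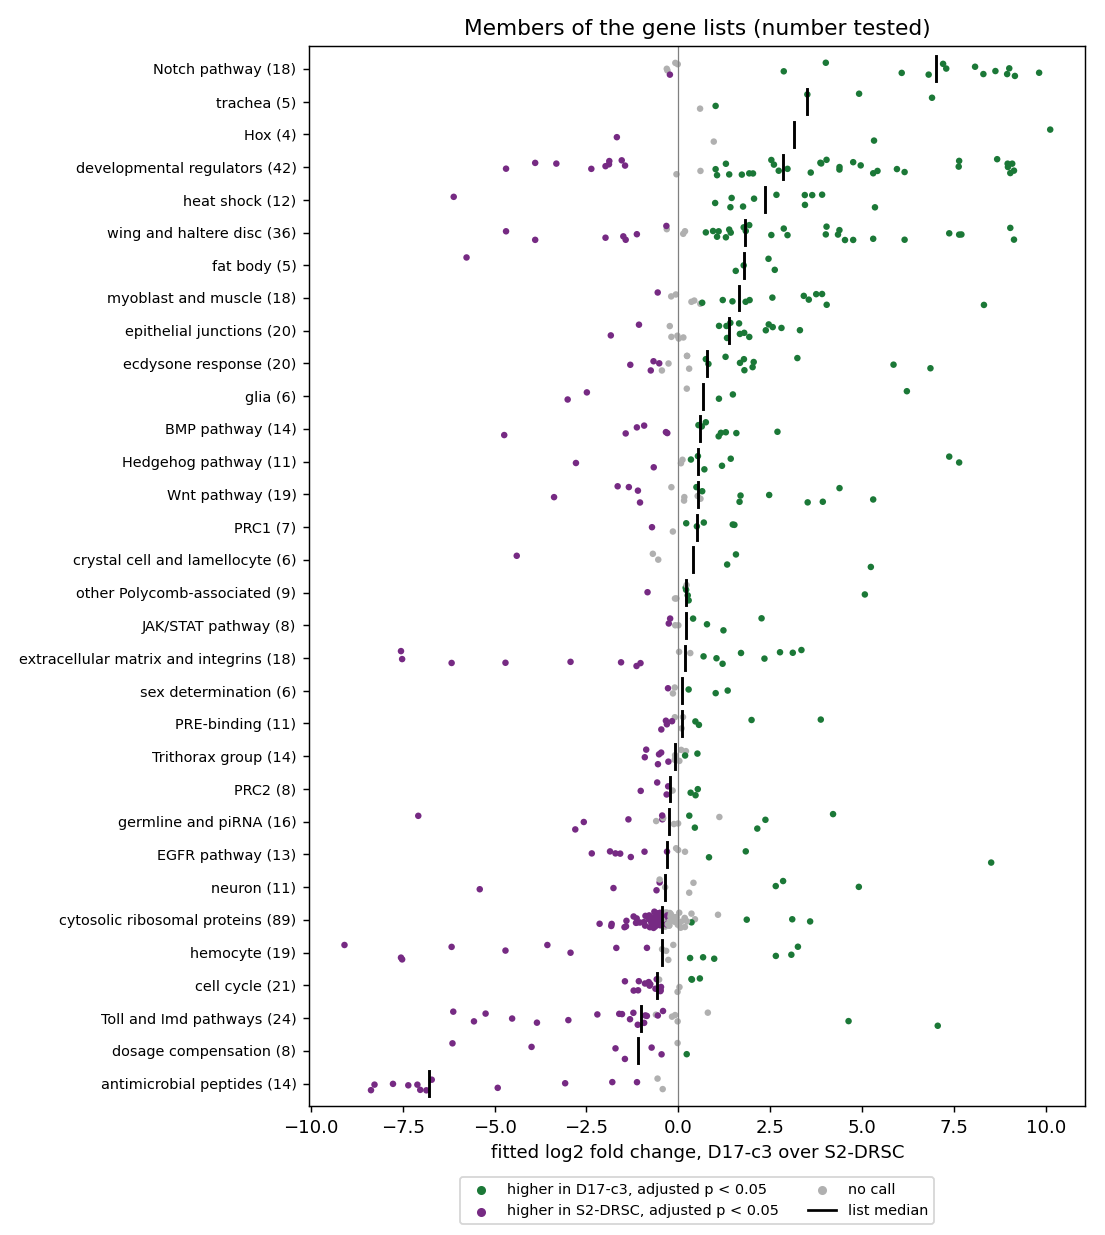
Fitted log2 fold change (D17-c3 over S2-DRSC) of each tested member of the 32 gene lists; green and purple points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. The Notch pathway has the highest median (7.01) and the antimicrobial peptides the lowest (-6.78).

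Few genes were expressed in 1 line only. Of 9047 genes with at least 1 CPM in all 4 libraries of a line, 102 (1.13%) were under 0.1 CPM in every S2-DRSC library and 62 (0.685%) were under it in every D17-c3 library. At this limit no list passed in 54 two-sided Fisher exact tests over 27 lists. The lowest unadjusted p was 0.0729, for antimicrobial peptides on in S2-DRSC, where CecB was the 1 member of 11 (odds ratio 14.7, adjusted p = 1). With a limit of 0.5 CPM the counts were 457 and 235, and 3 lists passed the Fisher exact test, developmental regulators (adjusted p = 0.00027) and Notch pathway genes (adjusted p = 0.0015) on in D17-c3 and antimicrobial peptides (adjusted p = 1.19e-07) on in S2-DRSC.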

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

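The tests of depth, of RNA from S2-DRSC cells, of the gene order, of the paralogs, of a segment that differs from the reference, and of copy number in the longest stretches were chosen only after the result was seen. A library was picked out where its gap to the nearest other library of its line, as a share of the range of the 4, passed Dixon's 95% limit, which chance gives in about 1 in 20 groups, or 17.6 of the 352 groups checked. There were 30 such values, 12 of them in D17-c3 replicate 2 and 12 in S2-DRSC replicate 4.

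D17-c3 replicate 2 stood far from the others in CPM of CG4766 (145, others 221 to 228), croc (386, others 513 to 526), Lsd-2 (224, others 182 to 188), en (29.5, others 49.9 to 54.1), corto (125, others 170 to 177), Sr-CI (45.2, others 9.77 to 14.9), Fas3 (1.05, others 2.23 to 2.32), zpg (0.0426, others 0.0939 to 0.101), ImpL1 (2.22, others 3.55 to 3.76), Egfr (151, others 402 to 451), et (4.92, others 2.18 to 2.64) and Hsp23 (8564, others 2786 to 3596). In D17-c3 replicate 1, Su(z)2 (94.9, others 78.2 to 80.4) and trx (508, others 460 to 468) were high.

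S2-DRSC replicate 4 stood far from the others in CPM of Nplp2 (2345, others 1764 to 1783), CecA1 (92.5, others 64.2 to 67.9), CecA2 (43.2, others 28.3 to 30.4), corto (5.52, others 4.46 to 4.6), phol (83.8, others 94.7 to 97), calypso (29.3, others 34.1 to 34.2), boi (237, others 269 to 275) and aos (85.8, others 127 to 135). It also did in the medians of the lists of antimicrobial peptides (3.72, others 3 to 3.05), other Polycomb-associated (-0.262, others -0.0606 to -0.0326), epithelial junction (-0.794, others -0.67 to -0.654) and JAK/STAT genes (-0.279, others -0.0696 to -0.0427). In other S2-DRSC libraries, dpp was high in replicate 1 (1.26, others 0.991 to 1.01), vn (6.78, others 6.17 to 6.24) and the share of the most abundant gene (1.39%, others 1.33% to 1.34%) in replicate 2, and Antp in replicate 3 (0.0106 CPM from 1 count, others 0).

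In D17-c3 replicate 2, 86 genes of at least 20 CPM were at least 2-fold above each other D17-c3 library and 114 were below each, against 0 to 11 and 0 to 4 in the other 7 libraries of either line. A difference in depth was argued against by its total count of 86.7 in units of 1000000, inside the range of 76.8 to 91.1 of the others. RNA from S2-DRSC cells was argued against because 81.4% of the raised genes rose by more than their whole S2-DRSC level, and gene length because 93.2% of the 249 genes that deviated 2-fold still did after the length trend was removed. S2-DRSC replicate 2 also had the highest level of its line for all 12 heat shock genes tested, at lower levels. The state of the flask stays open, since no biological explanation was tested and the labels describe the 4 flasks alike.

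The total of 97 shifted windows behind the 24 stretches is unlikely to come from a chance order of genes, since 0 of 1000 shuffles reached it (highest 13). The shuffles tested this total only, so single stretches, some of them only 50 genes long, can still be chance. Gene length and expression level were argued against as the whole source, since 90.7% of the shifted windows remained after both trends were removed. In stretches picked from every other gene, 67% of 1241 genes left out of the picking lay on the same side, and 74.1% of 490 genes for stretches of 100 genes or more. The bounds written for this test, under 70% against copy number and over 90% for it, were set too high, since the genes of the stretches themselves reached at most 80%, so neither share decides. Copy number and regional regulation cannot be told apart without DNA data.

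The genes p24-2 and Unc-115b were near 0 in D17-c3. Reads shared with the paralogs were argued against, since the sum of a gene and its paralog in D17-c3 was at most 43.5% of its lowest S2-DRSC sum (p24-2 with eca 132 ± 31.1 against 427 ± 17.2 CPM). The highest D17-c3 level of either gene was 0.398% of its lowest S2-DRSC level, a restatement of the values that prompted the test. Of the genes around them, CG32939 was also lower in D17-c3 (8.02 ± 6.06 against 49.3 ± 6.97 CPM), while CG18542 (2.53 ± 3.82 and 3.16 ± 3.81 CPM), eca (132 ± 31.1 and 174 ± 12.2 CPM) and Unc-115a (220 ± 17.1 and 210 ± 22.9 CPM) had counts in both lines. A segment that differs from the reference in D17-c3 and lower transcription cannot be told apart without DNA data.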

How the results depend on the processing

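The test on TPM after TMM scaling was chosen only after the results were seen. The counts of 4533 and 4192 called genes stayed within 1.5 times under all alternatives run. Of 133 named genes, 117 kept their direction and side of the threshold under all alternatives run on them and 14 lost their call under at least 1. Genes dome and tra changed sign on log2(TPM + 1) (0.01662 and 0.04138) and on log2(TPM + 0.1) (0.01671 and 0.04185). The median of all genes also moved on unscaled TPM, and whether this caused the change of sign was not tested. Where not stated otherwise, the cause of a change was not tested. Calls of genes at a few counts, such as abd-A, are limited by depth, and a filter tests fewer genes.

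Genes at least 2-fold higher in D17-c3 numbered 1921 with a filter of 1 CPM in 4 libraries and 1625 on TMM-scaled TPM, and those in S2-DRSC 1113 on log2(TPM + 1). Genes on only in D17-c3 and S2-DRSC numbered 457 and 235 with off under 0.5 CPM and 21 and 14 with on at 5 CPM or more. With off under 0.5 CPM, enrichment passed for developmental regulators (adjusted p = 0.00027) and Notch pathway genes (0.0015) in D17-c3 and antimicrobial peptides in S2-DRSC (1.19e-07) by Fisher exact tests.

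With an estimated correlation the limma camera adjusted p was 0.231 for developmental regulators and for Toll and Imd, 0.53 for disc, antimicrobial peptide and muscle, 0.706 for epithelial junction, 0.619 for Notch and dosage compensation and 0.791 for ribosomal protein genes. With limma fry, which does not compare a list with other genes, it was 0.000115 for PRC1, 0.00314 for PRE-binding, 0.000555 for other Polycomb-associated, 0.00576 for Trithorax, 1.13e-06 for Hox and hemocyte, 3.95e-06 for crystal cell and lamellocyte, 1.37e-06 for matrix, 1.69e-05 for glial, 0.000275 for germline, 7.49e-06 for tracheal, 2.26e-05 for ecdysone, 1.3e-05 for Wnt, 1.75e-06 for Hedgehog, 0.000405 for EGFR, 0.000838 for sex determination, 0.00703 for heat shock and 0.0165 for cell cycle genes. The replicate number as a block gave limma adjusted p-values of 0.0246 for heat shock and 0.0314 for cell cycle genes with the preset correlation (without the block 0.0742 for both, and 0.791 for both with an estimated correlation). Over all genes, residuals of same-numbered libraries of the lines were hardly correlated (0.011, 0.11, -0.039 and 0.052). Replicate 2 was the highest for 11 of 12 heat shock genes in D17-c3 and for all 12 in S2-DRSC, so an effect shared by number was not excluded for them.

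List counts moved as follows. Median-of-ratios factors: other Polycomb-associated in D17-c3 3. Library totals only: in S2-DRSC PRC2 2, PRE-binding 2, muscle 0, Notch 0, JAK/STAT 0 and sex determination 0, in D17-c3 Trithorax 5. No filter: in D17-c3 other Polycomb-associated 3, Trithorax 1, dosage compensation 0 and cell cycle 1, in S2-DRSC muscle 2 and fat body 2. Filter of 1 CPM in 4 libraries: in S2-DRSC PRC2 2, Hox 0, developmental regulators 4, disc 4, Notch 0, Wnt 3, JAK/STAT 0 and sex determination 0, in D17-c3 Hox 1, developmental regulators 17, muscle 6, glia 1 and ribosomal 2. DESeq2: in S2-DRSC crystal cell and lamellocyte 2 and Notch 2. limma-voom: crystal cell and lamellocyte in S2-DRSC 2. limma on log2(TPM + 1): in S2-DRSC PRC2 2, PRE-binding 0, Trithorax 3, Hox 0, muscle 0, Notch 0, JAK/STAT 0 and sex determination 0, in D17-c3 Trithorax 5 and dosage compensation 2. limma on log2(TPM + 0.1): the same S2-DRSC values of PRC2 2, PRE-binding 0, Trithorax 3, Hox 0, muscle 0, Notch 0, JAK/STAT 0 and sex determination 0, in D17-c3 Trithorax 6. TMM-scaled TPM: in D17-c3 other Polycomb-associated 3 and cell cycle 1, in S2-DRSC Hox 0 and sex determination 0. Replicate block: in D17-c3 other Polycomb-associated 3 and Trithorax 1, in S2-DRSC crystal cell and lamellocyte 2 and JAK/STAT 1.

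With each library left out, ranges were, in D17-c3, other Polycomb-associated 3 to 5 (3 without D17-c3 replicate 1 or 4 or any 1 S2-DRSC library), Trithorax 1 to 3 (1 without the same libraries), dosage compensation 0 to 1 (0 without D17-c3 replicate 1 or 4 or S2-DRSC replicate 1, 2 or 4), cell cycle 1 to 3 (1 without any 1 library but D17-c3 replicate 2) and ribosomal 4 to 9 (9 without D17-c3 replicate 2). In S2-DRSC they were PRC1 1 to 2 (2 without S2-DRSC replicate 4), fat body 1 to 2 (2 without D17-c3 replicate 1 or S2-DRSC replicate 4), Notch 1 to 2 (2 without D17-c3 replicate 1 or 4), sex determination 0 to 1 (1 only without D17-c3 replicate 2 or S2-DRSC replicate 4), crystal cell and lamellocyte 1 to 3 (3 without D17-c3 replicate 2), muscle 0 to 2 (2 without D17-c3 replicate 2, 0 without S2-DRSC replicate 3) and JAK/STAT 1 to 2 (1 without D17-c3 replicate 3 or S2-DRSC replicate 1, 2 or 3). Limma camera adjusted p-values with the preset correlation ranged from 0.033 to 0.0894 for heat shock (under 0.05 without D17-c3 replicate 1 or 3 or S2-DRSC replicate 2) and from 0.0448 to 0.0894 for cell cycle genes (under 0.05 without D17-c3 replicate 4). With an estimated correlation on all libraries the camera adjusted p was 0.791 for both. The X difference ranged from -0.0434 to -0.0326, with an exact p of 0.0571 without D17-c3 replicate 1, 2 or 4 or S2-DRSC replicate 3.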

Other observations

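None of the tests in this part was chosen after the result was seen. Genes that stood apart in D17-c3 replicate 2, named after their values were seen, included the small heat shock gene Hsp67Bc (317 CPM against 37.6 ± 17 in the other 3 D17-c3 libraries), the glutathione transferase gene GstD5 (67.1 against 11 ± 3.52), the transporter gene Orct2 (223 against 51.3 ± 9.9) and, below the others, the midline transcription factor gene sim (10.1 against 48.4 ± 6.62), Pvf1 (4.99 against 20.1 ± 2.21) and Notum, a secreted Wnt antagonist (7.15 against 34.3 ± 8.68).

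Each split of the 8 libraries into 4 and 4 was tested as the lines were, 35 splits in all. Only the real split, 1 of 35, called 8725 genes, and 1 of 35 called 4988 genes at least 2-fold, where the highest of the others called 0. A rank of 1 in 35 is the strongest these splits can give, so chance is unlikely for both counts but not excluded. Every other split mixes the lines and puts their difference into the spread within groups, so the 0 calls themselves add nothing to the rank. For the number of lists that passed camera, 8 of 35 splits reached the real 9 (highest other 11), so chance was not excluded for that number. Of the 7 other splits among them, 6 kept 3 libraries of each line together and so still held part of the difference between the lines, and 1 had 2 libraries of each line on either side. All splits with 2 libraries of each line on either side called 0 genes but passed 1 to 9 lists with the preset correlation. A pass with that correlation can thus occur without a contrast between the lines.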
